A study of Mus musculus with 16 samples.

How the data were processed

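Small RNA was measured in alveolar macrophages, the resident phagocytes of the airspaces, which were washed out of the lungs of 12-week-old mice. The mice lacked surfactant protein A (SP-A), a collectin of the airway lining that binds microbes. All were infected with about 450 CFU of Klebsiella pneumoniae, a bacterium that causes pneumonia, in 50 µl given by the oropharyngeal route. A part of them also received 10 µg of purified SP-A2 protein of the 1A0 variant, which had been expressed in CHO cells. Lavage was at 6 h. There were 4 groups of 4 libraries, namely infected females, infected females given protein, infected males and infected males given protein, with 4 animals per group, per the labels. The libraries were made with adapters ligated to small RNA and were read for 50 cycles on an Illumina HiSeq instrument. Females had been brought into the same phase of the estrous cycle, per the series' design text.

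The authors used TCC 1.14.0 with edgeR, per the series' design text, and called miRNAs at a false discovery rate of 0.1. The submitters' processing notes name CASAVA and edgeR without versions. The aligner, the genome build and the miRBase version are not given in the sources used here. The deposited tables hold a normalized signal per miRNA and library, made by the authors by dividing reads by 1 factor per library, as the values themselves show. Each of 4 comparison tables was scaled on its own, over the 8 libraries it compares, and carries the authors' p-values and q-values, per the file headers. A pair of further deposited tables holds the authors' fold, a ratio of 2 group means, for 178 miRNAs. In those tables the values of males and of females are the ones of the within-sex tables, so each sex was scaled apart from the other.

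Every value in a library was a whole multiple of the value of 1 read. With a tolerance of 0.001 reads, 100% of the values came out whole, and whole reads were recovered in this way. Recovered totals ran from 26515 to 705313 reads per library and table. A value of 1 read lay between 0.26 and 6.46 units of signal. On the scale of log2(value + 1), 1 read therefore stood at 0.33 in the deepest and at 2.90 in the shallowest library, and fold changes of miRNAs with few reads are imprecise. The same library appears in 2 tables, and its reads were not equal there. Totals differed by up to 1.26 times (infected female given protein, library 2), and the share of miRNAs with identical reads ran from 8.76% to 79.7% of those with a read in either table. Reads of near-identical miRNAs, such as miR-23a-3p and miR-23b-3p, were divided differently in the 2 tables (1478 and 2340 reads of miR-23a-3p in infected female 1). Values of such families are uncertain for that reason. So are those of miR-320-5p, with 13008 reads in the 4 infected females in the table of females and 10595 in the table of both sexes. Reads were treated as counted without molecular identifiers, and floors derived from them cover counting error only.

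The test fixed before the data were examined assumed counts. The tables held a normalized signal, so the alternative named in that plan was used. It was limma 3.58.1 with a trend on log2(value + 1), for miRNAs with a mean value of 1 or more, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.1 on the adjusted p. Each comparison used the 8 libraries of its own table, and effects are infection with protein minus infection, and male minus female. Effects over both sexes, over both treatments and their interaction were to be fitted only if all values had been scaled together. They had not been. They were fitted nonetheless on 2 joined tables, with a term for the table. A factor shared by a whole table cancels out in a log2 difference within it. On log2(value + 1) it does so only in part where values are low. A value of 1 read was up to 6.46 in the table of males and up to 2.24 in that of females. Joint estimates of miRNAs with few reads can therefore depend on the scale of a table. The joint fits were decided on after the tables were seen. edgeR 4.0.16 (quasi-likelihood test, TMM factors) and DESeq2 1.42.0 (Wald test) were run on the recovered reads as alternatives. Below, an adjusted p without a named tool is limma's. So is the SE of a fold, and limma moderates both toward a trend in spread fitted over all tested miRNAs.

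Groups of miRNAs were tested with camera (limma) at a preset correlation of 0.01, on log2(value + 1) in place of log2 CPM, for lists with 3 or more tested members, with adjustment over the lists. The 14 lists were fixed before the data were examined. They cover miRNAs induced by inflammation, macrophage polarisation, myeloid cells, neutrophils, erythrocytes, lymphocytes, airway and alveolar epithelium, endothelium and mesenchyme, the X chromosome, the Dlk1-Dio3 cluster, and the let-7, miR-17, miR-29 and miR-30, and miR-23-27-24 families. The lists share members. Where a miRNA is said to pass when adjusted over a list alone, the number of lists and comparisons was not adjusted for. The neutrophil list had 2 members and was not tested as a set. List tests on the effects over both sexes and over both treatments were added after the tables were seen.

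The miRNAs named in the text follow a rule fixed before the data were examined. Where fewer than 10 passed, all that passed and the 10 with the smallest unadjusted p are named, with miR-146a-5p, miR-155-5p, miR-21a-5p, miR-223-3p, miR-142a-3p and miR-451a in every comparison, and the 10 most abundant for the make-up of the libraries. Other miRNAs named were chosen after their values were seen.

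Each fit was tested on simulated reads in which 200 miRNAs were changed by a log2 fold of 2 or 4. For the protein effect in females, on 291 miRNAs, limma recovered 4.84% of the changes of 2 and 34.8% of those of 4, and edgeR recovered 16.7% and 90.6% on 137 miRNAs. For the protein effect in males (353 miRNAs) limma recovered 8.70% and 25.5%, and edgeR 25.0% and 81.2% on 125. For the sexes in infection (322 miRNAs) limma recovered 10.7% and 26.9%, and edgeR 23.3% and 74.1% on 137. For the sexes given protein (348 miRNAs) limma recovered 9.43% and 19.3%, and edgeR 33.3% and 68.2% on 126. For the interaction (317 miRNAs) limma recovered 8.86% and 19.0%. Over both sexes (319 miRNAs) limma recovered 31.0% and 52.9% of the protein effects, and over both treatments (334 miRNAs) 25.3% and 48.8% of the sex effects. edgeR recovered 18.4% and 41.8% of the interactions (200 miRNAs), 61.4% and 97.6% of the protein effects over both sexes (153 miRNAs) and 71.4% and 100% of the sex effects over both treatments (153 miRNAs). Among miRNAs left unchanged, limma called 13 of 150 for the protein over both sexes, 6 of 180 for the sexes in infection and at most 3 in each other fit, and edgeR called 5 of 68 for the protein over both sexes, 3 of 81 for the protein in females and at most 1 in each other fit. Within a table and for the interaction, a count of few or 0 by limma was therefore possible with many changes of these sizes present. In every fit but the interaction, edgeR recovered most changes of 4 among the fewer miRNAs it tested, and within a table at most 33.3% of the changes of 2. Regressed on the simulated changes, limma's folds had slopes of 0.58 to 0.70 and edgeR's of 0.87 to 1.08. Folds by limma on log2(value + 1) are therefore biased as well as imprecise.

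Alternatives were other scalings (library size, TMM, RLE and the iterative scheme of TCC), other filters, pseudocounts of 0.1 and 10, a threshold of 0.05, edgeR's exact test, 1 fit of all 16 libraries, the replicate number as a block, and each library left out in turn. TMM factors, the edgeR quasi-likelihood test and fits without the deepest male libraries were added after the data were seen. Splits of the 8 libraries into 4 and 4 (35 in all), or 100 drawn splits of 16 libraries, were fitted in the same way. Positions of hairpin genes are from GENCODE M21 on GRCm38, by gene name. No coordinates of the authors were used, and their build is not given in the sources used here. Hairpins were searched with blastn 2.17.0 against transcripts not annotated as miRNA, at 95% identity or more. No 45S ribosomal RNA sequence was among them, so a match of miR-6240, miR-6236, miR-5099 or other late miRBase entries to ribosomal RNA was not tested. A further table of fold changes repeats others and was not used here.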

Results

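The series addresses how the miRNAs of alveolar macrophages of male and female SP-A knockout mice differ 6 h after infection with K. pneumoniae, with or without SP-A2 protein. It holds 16 small RNA libraries, 4 per sex and treatment. Infected females had 94893 to 139154 recovered miRNA reads per library and infected females given protein 47892 to 127731. Infected males had 28934 to 408332 reads and infected males given protein 26515 to 692927. Depth in males was uneven, since infected male 3 had 408332 reads and protein-treated male 2 had 692927, against at most 60530 in the other male libraries. Between 132 and 552 miRNAs had a read in a library.

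**Figure D1:**
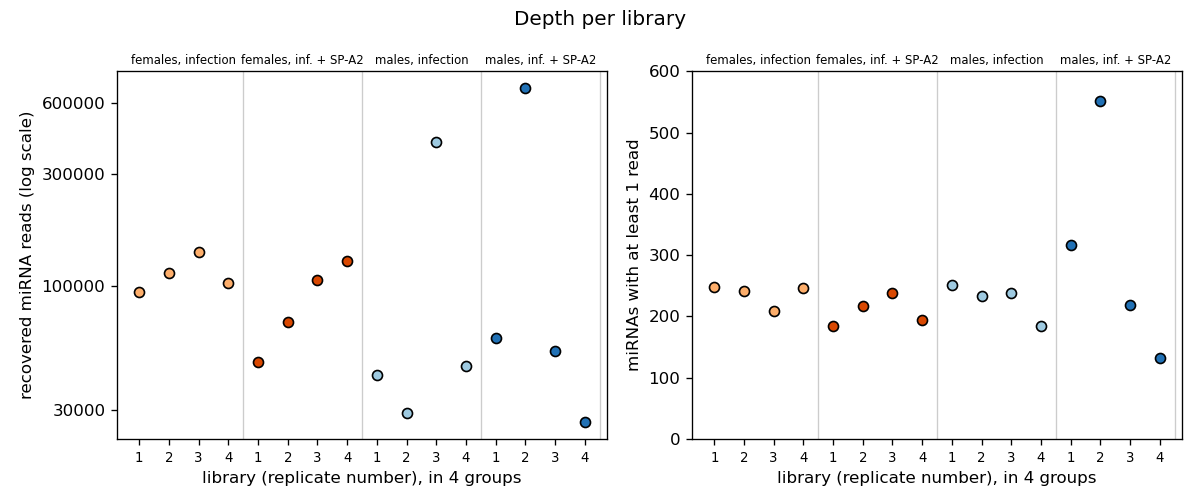
Recovered miRNA reads (left, log axis) and number of miRNAs with at least 1 read (right) for each of the 16 libraries, 1 point per library, in 4 groups. Infected male 3 (408332 reads) and protein-treated male 2 (692927 reads) lie far above the other males.

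The miRNA with the highest mean share over the 16 libraries was miR-21a-5p, which is abundant in macrophages and rises with inflammation, at 11.1% of reads. It was followed by 2 entries with high miRBase numbers, miR-6240 (10.7%) and miR-6236 (8.60%), and by miR-146b-5p (6.07%), a target of NF-κB and STAT3 signalling. The others among the 10 most abundant were let-7a-5p (3.59%), miR-30d-5p (3.35%), miR-125a-5p (2.86%), let-7f-5p (2.72%), miR-24-3p (2.70%) and miR-26a-5p (2.61%). These 10 held 45.5% to 65.8% of the reads of a library. Infected male 3 departed from this make-up, with 1.12% of reads for miR-6240 and 0.925% for miR-6236, and protein-treated male 2 had 30.6% of its reads in miR-21a-5p. The latter library had 5.39% in miR-6240, and without it miR-6240 had a higher mean share than miR-21a-5p. Replicates of a group correlated at 0.719 to 0.868 over 24 pairs, each seen in 2 tables (across miRNAs, which are not independent replicates), and no pair held identical values.

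In females, 3 abundant miRNAs were lower in animals given SP-A2 with the infection than in animals with the infection alone, and none was higher. miR-6240 fell by 0.98 on the log2 scale (SE 0.18, adjusted p = 0.000383), from 14.3% ± 1.65 to 8.25% ± 1.68 of reads (SD, n = 4 each). miR-320-5p, an entry of the hairpin Mir320, fell by 1.37 (SE 0.30, adjusted p = 0.00366), from 2.81% ± 0.634 to 1.22% ± 0.194 (SD, n = 4 each). Whether its reads stem from that hairpin was not tested. Its reads in the infected females depended on the table, with 13008 here and 10595 in the table of both sexes. miR-5099 fell by 1.09 (SE 0.28, adjusted p = 0.0262), from 4.18% ± 1.21 to 2.44% ± 1.28 (SD, n = 4 each). The SEs and p-values of these 3 rest in large part on the spread of the other miRNAs (66.3 degrees of freedom in limma's fit). They do not measure the spread among the 4 and 4 libraries alone. On the authors' scale the 4 protein-treated females lay below the 4 infected females for each of the 3, while as shares of reads those of miR-5099 overlapped. On GRCm38, Mir6240 lies on chromosome 5 from 114851948 to 114852064, Mir320 on chromosome 14 from 70443510 to 70443591, and Mir5099 on chromosome 12 from 36816205 to 36816278, all on the plus strand. None of these 3 hairpins overlapped another gene of that annotation, and whether the reads match ribosomal RNA was not tested.

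**Figure D2:**
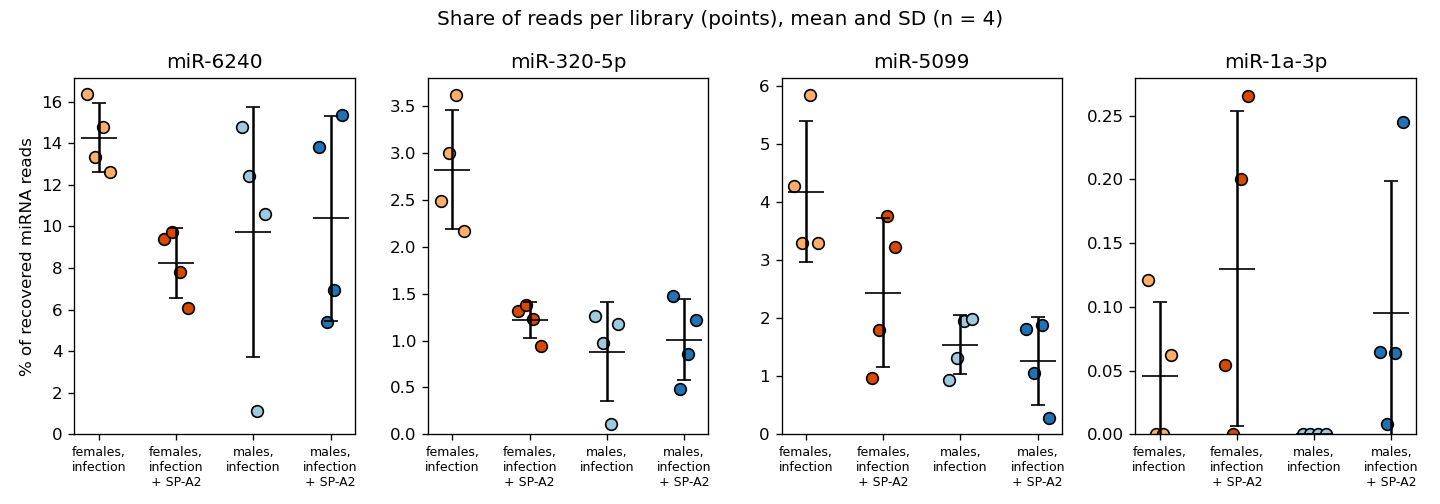
Share of recovered miRNA reads (%) of miR-6240, miR-320-5p, miR-5099 and miR-1a-3p in each library of the 4 groups; points are libraries, horizontal marks means and bars SD (n = 4). Infected females had 14.3% of reads in miR-6240 and protein-treated females 8.25%, and miR-1a-3p had 0 reads in all 4 infected males.

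These were 3 of 382 miRNAs tested by limma, of which 10 had an unadjusted p under 0.05 where 19.1 are expected by chance. edgeR and DESeq2 each called 1, miR-320-5p, which was also the only miRNA with a q-value under 0.1 in the authors' deposited table (0.00854). miR-6240 and miR-5099 did not pass by edgeR (adjusted p = 0.196 and 1) or DESeq2 (0.364 and 0.932). With edgeR's exact test (smallest adjusted p of the 3 0.108, for miR-320-5p) and with all 16 libraries in 1 fit (0.959 for each of the 3) none passed. The median log2 fold of all 382 was -0.19. Without infected female 3 only miR-6240 passed, without protein-treated female 1 miR-5099 did not, and without protein-treated female 2 there were 5 calls.

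Of the miRNAs next in rank in females, none passed (adjusted p = 0.779 each). miR-101a-3p (log2 fold about -3, SE 1.21), miR-101b-3p (-2.80, SE 1.38), miR-20a-5p of the growth-related miR-17-92 cluster (-3.44, SE 1.47), miR-1954 (-3.06, SE 1.37), miR-5098 (-1.65, SE 0.78) and miR-5100 (-2.04, SE 1.00) had negative estimates. That of miR-5100 was positive by edgeR (0.40) and DESeq2 (0.46), and its mean value was higher with protein (300 against 221). That of miR-101b-3p, which had reads in 2 of 4 protein-treated females, was -0.66 by edgeR. Those of miR-101a-3p (-1.58), miR-20a-5p (-2.17) and miR-1954 (-1.89) were also smaller by edgeR, and that of miR-5098 was -1.55. miR-712-5p, which is cut from a spacer of the ribosomal RNA precursor, had 141 reads in 3 protein-treated females and was listed at 0 in all infected females. The regulators of inflammation did not pass either. The log2 folds were 1.03 (SE 0.82) for miR-146a-5p and 0.04 (SE 1.68) for miR-155-5p, both induced by NF-κB, and -0.39 (SE 0.20) for miR-21a-5p. They were 0.06 (SE 0.57) for miR-223-3p, a regulator of neutrophils, -0.04 (SE 1.59) for the blood cell miRNA miR-142a-3p and -1.16 (SE 1.91) for the red cell miRNA miR-451a.

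No list of miRNAs moved as a group in females (camera, 12 lists). The macrophage polarisation list came nearest, with 10 of 12 members above 0 and an adjusted p of 0.167 (0.557 with an estimated correlation). The lists of endothelium and mesenchyme (7 of 9 above 0) and of the miR-23-27-24 clusters (6 of 8) had an adjusted p of 0.213 each. The other 9 lists had 0.772 each. They were inflammation (6 of 9 above 0), myeloid cells (5 of 10), erythrocytes (1 of 5), lymphocytes (1 of 5), epithelium (7 of 14), the X chromosome (8 of 25), let-7 (6 of 10), miR-17 (4 of 10) and miR-29 and miR-30 (3 of 10). Adjusted over the list alone, 0 miRNAs passed in any list. Without infected female 4 the polarisation, endothelium and mesenchyme, and miR-23-27-24 lists passed, without protein-treated female 2 the first 2 of these, and without infected female 3 the polarisation list. The Dlk1-Dio3 cluster had 2 tested members, 1 above and 1 below 0, and the neutrophil miRNAs also had 1 of each.

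In males, the miRNA with the smallest p between animals with and without SP-A2 was miR-1a-3p, a miRNA of heart and skeletal muscle. It had 39, 56, 34 and 65 reads in the 4 protein-treated males and was listed at 0 in all 4 infected males, including the one with 408332 reads, where 3 counts would be a share of 0.000735%. It did not pass limma's test (adjusted p = 0.448, and 0.337 to 0.891 under the alternatives with limma) and passed that of DESeq2 (adjusted p = 1.51e-05). In females it had 179 reads in 2 of 4 infected animals and 578 in 3 of 4 given protein (log2 fold 2.04, SE 1.53, adjusted p = 0.779). In the authors' deposited table it was the only miRNA with a q-value under 0.1 (3.56e-05). Its genes on GRCm38 are Mir1a-1 on chromosome 2 from 180389048 to 180389124, outside other genes, and Mir1a-2 on chromosome 18 from 10785481 to 10785552, in an intron of the transcript that also hosts Mir133a-1 and antisense to an intron of Mib1.

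Of 399 miRNAs tested in males, limma called 0, with 7 at an unadjusted p under 0.05, where about 20 are expected by chance. edgeR called 0 and DESeq2 1. Without the 2 deepest male libraries, a setting chosen after the depths were seen, limma called 2 miRNAs, miR-143-3p of smooth muscle and miR-23b-3p. The miRNAs next in rank all had an adjusted p of 0.919. Positive estimates were those of miR-34c-5p of ciliated epithelium (3.89, SE 1.65), miR-106b-5p (3.11, SE 1.39), miR-361-3p (3.82, SE 1.73) and miR-143-3p (2.88, SE 1.33). miR-1983 (-3.29, SE 1.66) and miR-1194 (-3.58, SE 1.83) had negative ones. By edgeR the folds were smaller, at 0.87 for miR-143-3p, 2.19 for miR-34c-5p, 2.29 for miR-106b-5p and -1.77 for miR-1983. miR-672-5p (59 reads), miR-450b-3p (103) and miR-21a-3p (65) were seen in 3 protein-treated males each and were listed at 0 in infected males. The log2 folds were 0.04 (SE 0.96) for miR-146a-5p, -2.16 (SE 1.52) for miR-155-5p, 0.36 (SE 0.48) for miR-21a-5p, -0.54 (SE 0.84) for miR-223-3p, 1.57 (SE 1.52) for miR-142a-3p and 0.60 (SE 1.88) for miR-451a, and those of miR-146a-5p, miR-223-3p and miR-451a were of the opposite sign by DESeq2.

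None of 13 lists passed in males. The epithelial list had 12 of 14 members above 0 and an adjusted p of 0.247, and endothelium and mesenchyme had 4 of 7 and 0.263. The other lists had 0.577 (miR-17, 7 of 12) or 0.811 (inflammation 6 of 9, polarisation 7 of 13, myeloid 5 of 10, erythrocytes 5 of 5, lymphocytes 1 of 3, X chromosome 14 of 28, Dlk1-Dio3 2 of 5, let-7 4 of 10, miR-29 and miR-30 6 of 10, and miR-23-27-24 6 of 9). Without infected male 2 or infected male 3 the epithelial and the endothelium and mesenchyme lists passed, and without protein-treated male 1 or 4 the epithelial list. Both neutrophil miRNAs were below 0. Adjusted over the list alone, miR-1a-3p passed in the list of endothelium and mesenchyme (adjusted p = 0.00786), and no miRNA passed in another list.

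The response to the protein was then set side by side in the 2 sexes. In males the 3 miRNAs that fell in females had log2 folds of 0.60 (SE 0.57) for miR-6240, 0.70 (SE 0.74) for miR-320-5p and -0.42 (SE 0.62) for miR-5099. Without infected male 3, where miR-6240 and miR-320-5p were far below the other infected males, the first 2 were -0.30 (SE 0.37) and -0.18 (SE 0.64), and without protein-treated male 4 that of miR-5099 was 0.17. The difference between the sexes, male minus female, was 1.58 (SE 0.78) for miR-6240, 2.07 (SE 0.85) for miR-320-5p and 0.66 (SE 0.70) for miR-5099, each with an adjusted p of 0.982, so the responses were not shown to differ. Without infected male 3 it was 0.68 (SE 0.43) for miR-6240 and 1.19 (SE 0.57) for miR-320-5p. Over 348 miRNAs limma called 0 interactions, with 10 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 1 (miR-467h). All 10 had positive estimates, and the median of all 348 was 0.26. Whether the unlike scales of the male and female tables contribute to this was not tested. The smallest p values were those of miR-672-5p (6.73, SE 2.20), which lies in an intron of Nexmif on the X chromosome, and of miR-450b-3p (5.59, SE 1.89). Both passed when adjusted over the X chromosome list alone (smallest adjusted p = 0.0888). The others among the 10 smallest, besides miR-320-5p, were miR-200a-5p (3.77, SE 1.49), miR-106b-5p (4.10, SE 1.71), miR-5098 (3.65, SE 1.63), miR-101a-3p (3.63, SE 1.66), miR-141-3p (5.17, SE 2.37), miR-3473d (3.70, SE 1.69) and miR-6937-5p (2.73, SE 1.32). Those of the regulators were -0.99 for miR-146a-5p, -2.19 (SE 2.24) for miR-155-5p, 0.76 (SE 0.64) for miR-21a-5p, -0.60 (SE 1.07) for miR-223-3p, 1.61 (SE 2.35) for miR-142a-3p and 1.76 (SE 2.29) for miR-451a.

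None of 12 lists passed in the interaction. Polarisation (3 of 12 members above 0) and miR-23-27-24 (3 of 8) had an adjusted p of 0.387. Inflammation (4 of 8), epithelium (8 of 13) and miR-17 (7 of 11) had 0.671, and myeloid cells (6 of 10), erythrocytes (5 of 5) and let-7 (5 of 10) had 0.788. Lymphocytes (2 of 3), endothelium and mesenchyme (3 of 9), the X chromosome (15 of 26) and miR-29 and miR-30 (8 of 10) had 0.841. The miR-23-27-24 list passed without protein-treated male 2 and the polarisation list without infected male 4. Across 300 miRNAs tested in both sexes, Pearson's r of the 2 sets of estimates was 0.0952 (permutation p = 0.287) and Spearman's rho 0.0802 (permutation p = 0.327), from 100 permutations of the treatment labels, and 156 miRNAs (52%) had the same sign. The median SE of a fold was 1.20 in females and 1.31 in males, so the estimates could correlate weakly even if the true responses agreed, and agreement was not decided.

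Over both sexes, no miRNA passed for the protein. limma called 0 of 348, with 8 at an unadjusted p under 0.05, and edgeR and DESeq2 called 0. The smallest p values were those of miR-1a-3p (4.26, SE 1.34), miR-223-5p (-3.20, SE 1.11), miR-22-3p (0.85, SE 0.34), miR-148b-3p (-2.52, SE 1.03), miR-34c-5p (2.60, SE 1.11), miR-20a-5p (-2.68, SE 1.19), miR-5099 (-0.76, SE 0.35), miR-98-5p (-2.29, SE 1.07), miR-1964-3p (2.13, SE 1.06) and miR-3968 (-2.13, SE 1.08), each with an adjusted p of 0.985. Without protein-treated female 2, miR-1a-3p passed. The log2 folds were 0.53 (SE 0.62) for miR-146a-5p, -1.06 (SE 1.11) for miR-155-5p, -0.02 (SE 0.32) for miR-21a-5p, -0.24 (SE 0.52) for miR-223-3p, 0.76 (SE 1.16) for miR-142a-3p and -0.28 (SE 1.13) for miR-451a. Those of miR-21a-5p and miR-223-3p were of the opposite sign by edgeR and DESeq2, and that of miR-21a-5p also under 3 other scalings.

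For the protein over both sexes, the epithelial list and the list of endothelium and mesenchyme passed camera in the upward direction, in list tests added after the tables were seen. Members of the epithelial list were above 0 in 10 of 13 cases and those of endothelium and mesenchyme in 6 of 9, each with an adjusted p of 0.0913 by camera. The adjusted p was 0.997 for both with an estimated correlation (0.179 and 0.300, against the preset 0.01) and 0.996 for both by the set test fry. As many lists were called in 28 of 100 drawn splits. In females alone 7 of 14 epithelial members were above 0, against 12 of 14 in males alone. Leading members of the 2 lists were miR-34c-5p and miR-1a-3p. The polarisation (7 of 12), myeloid (3 of 10) and X chromosome (9 of 26) lists had 0.927 and the remaining 7 had 0.997. Adjusted over the list alone, miR-1a-3p passed among endothelium and mesenchyme (adjusted p = 0.0351), and miR-223-5p passed among the neutrophil (0.0153) and myeloid (0.0766) miRNAs. Over all miRNAs miR-223-5p had 0.985. The other of the 2 neutrophil miRNAs, miR-223-3p, was more abundant (mean CPM 3746 against 168). Its fold was -0.24 by limma, 0.14 by edgeR and 0.17 by DESeq2. Both lists kept their call only without infected male 2 or 3, infected female 1 or 4 or protein-treated female 2. It fell to 1 list without protein-treated female 1 and to 0 without each other library.

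Between infected males and infected females, 2 miRNAs were lower in males and none was higher. miR-5099 was lower by a log2 fold of -1.57 (SE 0.38, adjusted p = 0.0434) and miR-320-5p by -2.02 (SE 0.53, adjusted p = 0.0576), and the 4 males lay below the 4 females for both. Without infected male 3 the log2 fold of miR-320-5p was -1.10 (SE 0.32) and did not pass (adjusted p = 0.140), and that of miR-5099 was -1.63 (SE 0.29) and passed. In this comparison miR-6240 had -1.20 (SE 0.40) and did not pass (adjusted p = 0.398), and without infected male 3 it had -0.26 (SE 0.17). The next in rank was miR-1291 (-4.34, SE 1.30, adjusted p = 0.186), with 13 reads in the males and 484 in the females. Its hairpin on GRCm38, on chromosome 15 from 98519762 to 98519878 on the minus strand, lies in an intron of Kansl2 and overlaps the small nucleolar RNA gene Snora34. It shares 92 of its 117 bases with Snora34 at 100% identity. Its reads could be fragments of that RNA, but where they lie within the hairpin was not tested. miR-143-3p of smooth muscle had -2.89 (SE 1.00, adjusted p = 0.427), with reads in 3 of 4 males. Its fold was -1.12 by edgeR and ran from -4.10 to -0.78 with 1 library left out.

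**Figure D3:**
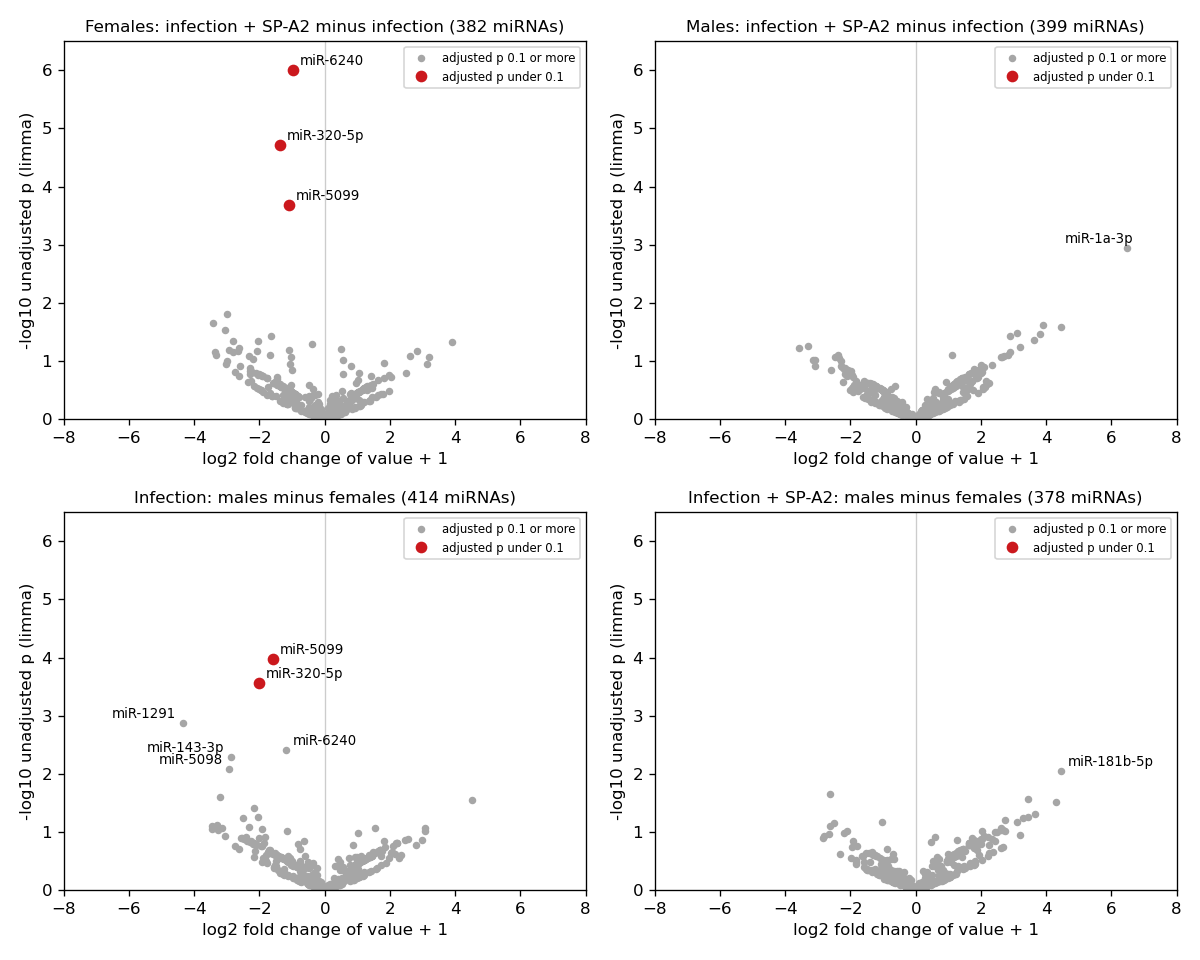
Log2 fold change (x axis) against -log10 of limma's unadjusted p (y axis) for every tested miRNA in 4 comparisons of 4 libraries with 4; red points passed at an adjusted p under 0.1. The protein comparison in females had 3 such miRNAs, the comparison of infected males with infected females 2, and the other 2 comparisons 0.

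These were 2 of 414 miRNAs tested, with 9 at an unadjusted p under 0.05, where 20.7 are expected by chance. edgeR called 2 (miR-1291 and miR-5099) and DESeq2 3 (miR-1264-3p, miR-1291 and miR-5099), the same 3 names as at a q-value under 0.1 in the authors' deposited table. miR-320-5p did not pass by edgeR (adjusted p = 0.994) or DESeq2 (0.974). Without infected female 3 limma called 0, without infected female 1 it called 1 (miR-320-5p), and without infected male 3 it called 2 (miR-5099 and miR-143-3p). It called 4 without infected male 1, infected male 4 or infected female 2. With TMM factors it called 5 (miR-143-3p, miR-1291 and miR-6240 were added). It called 1 (miR-5099) with a pseudocount of 0.1, with a mean of 50 or more reads and at a threshold of 0.05, and 0 with no filter, with the replicate number as a block and with all 16 libraries in 1 fit.

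Both miRNAs were also among the 3 that fell in females given protein, a comparison with the same infected females. Of 338 miRNAs tested in both, 2 were called in both, of which miR-320-5p was not called between the sexes without infected male 3 and neither was without infected female 3. Independent lists would give an overlap of 0.0178, a value that leaves out the shared females. Unchanged groups simulated against shared females gave 0, but both comparisons had a call in only 1 of 100 simulations. With the infected females divided into pairs, 1 pair for each comparison, the overlap was 0 in 6 of 6 divisions, but both comparisons had a call in 0 of the 6. Neither weighs the overlap of 2, and how much of it comes from the shared females is not known.

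Other miRNAs did not pass between infected males and females (adjusted p from 0.569 to 0.987). They were miR-5098 (-2.93, SE 1.07), miR-199b-3p of mesenchyme (-3.22, SE 1.40), miR-709 (-2.16, SE 1.03), miR-125b-5p (-2.04) and miR-1264-3p (4.50, SE 2.00), which had 104 reads in 3 males and 1 in a female. miR-709 and miR-125b-5p had reads in 3 of 4 males, and their folds were smaller by edgeR (-0.76 and -0.13). So were those of miR-199b-3p (-1.37) and miR-5098 (-2.03). Reads of miR-125b-5p were 1042 in the females and 1040 in the males. The log2 folds were 0.82 (SE 0.96) for miR-146a-5p, 1.84 (SE 1.36) for miR-155-5p, -0.24 (SE 0.29) for miR-21a-5p, 1.01 (SE 0.61) for miR-223-3p, 0.07 (SE 1.60) for miR-142a-3p and -1.11 (SE 1.89) for miR-451a. None of 13 lists passed. Endothelium and mesenchyme had 7 of 8 members below 0 and an adjusted p of 0.394, and miR-143-3p passed when adjusted over that list alone (adjusted p = 0.0413). Inflammation (4 of 7 above 0), polarisation (8 of 13), myeloid cells (6 of 10), epithelium (6 of 15), Dlk1-Dio3 (3 of 4), miR-29 and miR-30 (1 of 10) and miR-23-27-24 (5 of 8) had 0.5. Let-7 (4 of 10) had 0.566, erythrocytes (1 of 4) and the X chromosome (13 of 27) 0.651, lymphocytes (2 of 5) 0.913 and miR-17 (6 of 10) 0.960. Endothelium and mesenchyme passed without infected male 3, as did let-7, and without infected female 2 or infected female 3. Both neutrophil miRNAs were above 0.

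Between males and females given protein, no miRNA passed. limma called 0 of 378, with 5 at an unadjusted p under 0.05 where 18.9 are expected by chance, edgeR and DESeq2 called 0, and so did the authors' deposited table at a q-value under 0.1. The smallest p was that of miR-181b-5p, a lymphocyte miRNA, with 400 reads in 4 males and 15 in 2 females (4.44, SE 1.62). It was followed by miR-23b-3p (-2.64, SE 1.12), miR-106b-3p (3.43), miR-148a-3p (3.30, SE 1.69), miR-101a-3p (2.73, SE 1.43) and miR-5099 (about -1, SE 0.54), all with an adjusted p of 0.958. The fold of miR-23b-3p was -0.72 by edgeR and ran from -3.51 to -0.18 with 1 library left out. By edgeR those of miR-181b-5p (3.26), miR-106b-3p (1.52), miR-148a-3p (2.19) and miR-101a-3p (1.41) were also smaller. miR-672-5p (59 reads), miR-1843a-3p (62), miR-450b-3p (101) and miR-21a-3p (79) were seen in 3 males each and listed at 0 in the females. The log2 folds were -0.15 (SE 0.87) for miR-146a-5p, -0.30 (SE 1.78) for miR-155-5p, 0.59 (SE 0.38) for miR-21a-5p, 0.49 (SE 0.80) for miR-223-3p, 1.87 (SE 1.44) for miR-142a-3p and 0.90 (SE 1.92) for miR-451a, and that of miR-451a was negative by DESeq2.

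None of 13 lists passed between the sexes given protein. Endothelium and mesenchyme (8 of 9 below 0) and miR-17 (8 of 12 above 0) had an adjusted p of 0.327, and lymphocytes (2 of 3), the X chromosome (17 of 25) and let-7 (5 of 10) had 0.506. Polarisation (7 of 13), myeloid cells (7 of 10), erythrocytes (3 of 4) and miR-23-27-24 (5 of 9) had 0.654, Dlk1-Dio3 (2 of 3) 0.785, inflammation (5 of 10) and epithelium (8 of 15) 0.878, and miR-29 and miR-30 (6 of 10) 0.962. Endothelium and mesenchyme and let-7 passed without protein-treated female 2. Both neutrophil miRNAs were above 0. Adjusted over the list alone, miR-181b-5p passed among the lymphocyte miRNAs (adjusted p = 0.0268).

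Over both treatments, the list of endothelium and mesenchyme passed camera with lower values in males, in a list test added after the tables were seen. Of 9 members 8 were below 0, with a median log2 fold of -1.03 and an adjusted p of 0.0292 by camera. The adjusted p was 0.812 with an estimated correlation (0.315) and 0.838 by fry, and 63 of 100 drawn splits called as many lists. The call was lost without infected male 1 or 4, infected female 4, protein-treated male 1 or 2 or protein-treated female 4, and 2 lists passed without infected male 3. The X chromosome list had 20 of 27 members above 0 and an adjusted p of 0.371, and the others had 0.557 to 0.922.

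No single miRNA passed over both treatments. limma called 0 of 356, with 17 at an unadjusted p under 0.05 where 17.8 are expected by chance, edgeR called 0 and DESeq2 2. Those 2 were miR-1291 (-3.50, SE 0.91, adjusted p = 0.234 by limma) and miR-1843a-3p (3.36, SE 1.12, adjusted p = 0.674). miR-5099 had -1.30 (SE 0.38, adjusted p = 0.408). The next were miR-148a-3p (2.51), miR-106b-3p (2.63, SE 1.07), miR-199b-3p (-2.86, SE 1.18), miR-511-5p, which lies in the mannose receptor gene of macrophages (1.87, SE 0.79), miR-145a-3p (-2.07, SE 0.91), miR-224-5p (1.90, SE 0.84) and miR-671-3p (1.84, SE 0.82), each with an adjusted p of 0.933. The log2 folds were 0.33 (SE 0.65) for miR-146a-5p, 0.77 (SE 1.11) for miR-155-5p, 0.17 (SE 0.32) for miR-21a-5p, 0.75 (SE 0.53) for miR-223-3p, 0.97 (SE 1.15) for miR-142a-3p and -0.10 (SE 1.13) for miR-451a, and that of miR-146a-5p was negative by edgeR and DESeq2.

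In the authors' deposited table of folds, the median of the male over the female value was 1.49 in infection and 1.57 in infection with protein over 178 miRNAs, where males and females had been scaled apart. In the tables scaled over both sexes the same miRNAs had medians of 0.948 and 1.09, which such a scaling itself places near 1. The median of protein over infection in the authors' deposited table was 0.991 in males and 0.967 in females.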

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

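The tests of scaling, of other late miRBase entries, of sequencing depth and of muscle RNA in this part were chosen only after the result was seen. Those of separate scaling and of splits of the libraries were planned.

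miR-6240, miR-320-5p and miR-5099 fell in females given protein, although without infected female 3 only miR-6240 passed, without protein-treated female 1 miR-5099 did not, and without protein-treated female 2 there were 5 calls. The 3 folds stayed below 0 under library size, TMM, RLE and iterative scaling. The value nearest to 0 was -0.81 for miR-6240 (SE 0.16, library size), where miR-5099 had an adjusted p of 0.0930 (0.00782 to 0.0930 over the 4 scalings). These scalings moved the 3 folds little, so the choice among them does not account for the fall. All 4 are relative to the reads of a library, so a change in its total small RNA was not tested. A change shared by all abundant entries with a miRBase number of 2000 or more cannot cover miR-320-5p, which is not such an entry, and stays open for miR-6240 and miR-5099. The 11 others had a median log2 fold of -0.37, too near to -0.5 for a decision. The SE used for this (0.21) is that of their mean and takes entries of the same libraries as independent. By limma 11 of 11 were below 0, where the median of all 382 miRNAs was itself -0.19. By edgeR 9 were (median -0.14) and by DESeq2 7 (median -0.095). The most abundant of them were at -0.19 (SE 0.21, miR-6236), -0.09 (SE 0.29, miR-5126) and -0.11 (SE 0.38, miR-3963) by limma. The less abundant miR-5100 (-2.04, SE 1.00), miR-5098 (-1.65, SE 0.78) and miR-3470b (-1.03, SE 0.59) were lower. A fall as large as that of miR-6240 was thus not seen in all of them, while a smaller shared change stays open. Chance could not be excluded either, since 7 of 35 splits of the 8 libraries called as many miRNAs (3 in the real split, 12 in the highest other, whose make-up was not examined). A response to the protein is an untested hypothesis.

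In the authors' deposited table, the median male over female fold was 1.49 in infection and 1.57 with protein. The same 178 miRNAs had medians of 0.948 and 1.09 where males and females were scaled in 1 table, but such a scaling centres the ratio near 1 whatever the cause, so this decides nothing. The mean sum of values was 148467 in infected males and 107663 in infected females within the separately scaled tables, and 165375 and 96116 with protein. With each sex on its own scale, a median fold above 1 is by itself no sign of a difference between the sexes. The higher sums of values in males go the same way as that fold. Whether the sexes also differed in level cannot be told, since no scale common to both sexes was measured other than by centring.

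miR-1a-3p had reads in 4 of 4 males given protein and in 0 of 4 infected males. Depth is argued against, since at the lowest share among the protein-treated males 33 reads would be expected in the deepest infected male library and 42.4 over the 4, and 0 were seen. Muscle RNA carried into the lavage of protein-treated males stays open. miR-133a-3p, the other abundant muscle miRNA, had a log2 fold of 1.20 (SE 1.68), with 46 reads in 1 infected male and 15 reads in 3 males given protein, too few to decide. No biological explanation was tested.

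Chance was not excluded for the counts above 0. Between infected males and females 4 of 35 splits called as many miRNAs (2 in the real split, 2 in the highest other). Where the real split called 0, every split calls as many and nothing is decided, which holds for 35 of 35 splits for the protein in males (highest other 1) and for the sexes given protein (6), and 100 of 100 drawn splits for the protein over both sexes (2), the sexes over both treatments (2) and the interaction (3). For lists, 28 of 100 splits called as many for the protein over both sexes (2 in the real split, 5 in the highest other) and 63 of 100 for the sexes over both treatments (1 and 7). The remaining comparisons had 0 lists in the real split, so that 35 of 35 splits called as many and nothing is decided (highest other 7 for females, 5 for males, 4 for the sexes in infection, 8 for the sexes given protein), as do 100 of 100 for the interaction (5).

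In 18 of 167 sets of 4 values (a measure of depth or 1 miRNA, in 1 group) 1 library stood apart from the other 3 by a large part of the range. For independent normal values about 1 in 20, or 8.35, would be flagged. These sets reuse the same 16 libraries, some hold zeros and many of the miRNAs were picked by a small p. The 18 can therefore not be weighed against 8.35. The share of the range taken by that gap was 0.956 for the reads of infected male 3 and 0.949 for those of protein-treated male 2. Infected male 3 also stood apart in its percent of miR-6236 (0.899, at 0.925% of reads). Infected female 3 stood apart in its number of miRNAs with reads (0.850, at 208) and its percent of miR-125a-5p (0.950, at 2.66%), and infected female 4 in its percent of miR-24-3p (0.839, at 2.91%) and its value of miR-101b-3p (0.831, at 17.5).

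Protein-treated female 1 stood apart in miR-451a, at 29.1 in the table of females (0.906) and 33.2 in the table of both sexes (0.901), and protein-treated female 2 in miR-181b-5p (0.887, at 26.9). Infected male 4 stood apart in miR-1194 (0.875, at 0). In miR-1194 protein-treated male 2 (at 1.22), and in miR-1264-3p infected female 1 (at 1.54), were the only libraries of their group with a read, which gives a share of 1. Protein-treated male 4 stood apart in miR-23b-3p (0.861, at 0), miR-106b-3p (0.882, at 334) and miR-21a-3p (0.890, at 0), and protein-treated male 2 in miR-101a-3p (0.847, at 208) and miR-21a-5p (0.833, at 54981).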

How the results depend on the processing

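Tests with TMM factors, with the edgeR quasi-likelihood test and without the deepest male libraries, list tests over both sexes and both treatments, and folds of single miRNAs with a library left out, by the edgeR exact test and with all 16 libraries in 1 fit, were chosen only after the result was seen. The cause of a difference named here was not tested, except where fewer libraries or other miRNAs were tested by construction. Depth limits the values, since 1 read stood at up to 2.90 on the log2(value + 1) scale. The median log2 fold of all tested miRNAs moved with the scaling, from -0.07 (library size) to -0.25 (iterative) in females given protein (as deposited -0.19), from -0.10 to 0.15 in males (0.03), from -0.06 to -0.27 for the sexes in infection (-0.17) and from -0.06 to 0.31 with protein (0.13).

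The 3 calls for the protein in females stayed within 1.5 times under 9 of 14 alternatives. They were 1 with a mean of 50 or more reads, with DESeq2 and with edgeR quasi-likelihood (miR-320-5p each time), 0 with the edgeR exact test and 0 with all 16 libraries in 1 fit. With 1 library left out they ran from 1 (infected female 3) to 5 (protein-treated female 2). The 0 calls in males became 1 with DESeq2 and 2 without the deepest male libraries, and were 0 to 0 with 1 library left out. The 2 calls between infected males and females became 5 with iterative scaling and with TMM, 0 with no filter, with the replicate block and with all 16 libraries, and 1 with 50 or more reads, with a pseudocount of 0.1 and at a threshold of 0.05. They ran from 0 (without infected female 3) to 4 (without infected male 1, infected male 4 or infected female 2), with 1 without infected female 1. The 0 calls between the sexes given protein were 0 under 15 of 15 alternatives by limma, edgeR and DESeq2 (5 at an unadjusted p under 0.05 by limma) and 0 to 0 with a library left out. Over both sexes the 0 calls for the protein were 0 under 13 of 13 and 0 to 1 with a library left out (1 without protein-treated female 2). The 0 calls for the sexes over both treatments became 2 with DESeq2, and the 0 interactions 1 with DESeq2, both 0 to 0 with a library left out. The correlation of the 2 protein responses was 0.0802 to 0.106 under alternatives and 0.0349 to 0.117 with a library left out.

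List calls were 2 for the protein in females and 2 for the interaction under library size scaling (0 as reported), and 1 for the sexes given protein with no filter or a pseudocount of 10 (0 as reported). The 2 for the protein over both sexes became 0 with an estimated correlation, fry, library size scaling and pseudocounts of 0.1 and 10, and 1 with no filter. The 1 for the sexes over both treatments became 0 with an estimated correlation, fry and no filter. With a library left out lists ran from 0 to 3 for females, 0 to 2 for males, for the sexes in infection, for the sexes given protein, for the protein over both sexes and for the sexes over both treatments, and 0 to 1 for the interaction. The libraries concerned are named in the report.

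Of 2796 values of single miRNAs under alternatives, 2654 kept sign and side of the threshold, 32 lost a call, 27 gained one and 83 changed sign, all 83 in miRNAs not called in that comparison. Of these, 1343 are values with a library left out, with 1274 kept, 7 calls lost, 10 gained and 52 signs changed. For the protein in females miR-142a-3p became 0.034 (library size), 0.18 (DESeq2) and 0.11 (both edgeR tests), and miR-5100 0.46 (DESeq2) and 0.40 (both edgeR tests). In males miR-146a-5p became -0.10 (library size), -0.074 (DESeq2), -0.20 (both edgeR tests) and -0.13 (without the deepest libraries), where miR-21a-5p became -0.021 and miR-6240 -0.15, and DESeq2 gave 0.0024 for miR-223-3p and -0.22 for miR-451a. Between the sexes given protein miR-146a-5p became 0.017 (iterative and TMM) and miR-451a -0.088 (DESeq2), and without the deepest library miR-21a-5p became -0.030 there and miR-142a-3p -0.042 between infected males and females. Over both sexes miR-21a-5p became 0.026 (RLE), 0.077 (iterative and TMM), 0.25 (DESeq2) and 0.15 (edgeR), and miR-223-3p 0.17 (DESeq2) and 0.14 (edgeR). Over both treatments miR-146a-5p became -0.064 (DESeq2) and -0.17 (edgeR), and miR-21a-5p -0.23 without the deepest libraries.

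With 1 library left out, signs changed within these ranges. For the protein in females they were -1.13 to 1.21 for miR-155-5p, -0.26 to 0.48 for miR-223-3p and -1.30 to 1.21 for miR-142a-3p. In males they were -0.26 to 0.40 for miR-146a-5p, -0.24 to 0.75 for miR-21a-5p, -1.01 to 0.42 for miR-223-3p, -0.28 to 1.38 for miR-451a, -0.30 to 1.00 for miR-6240, -0.18 to 1.06 for miR-320-5p and -0.66 to 0.17 for miR-5099. Between infected males and females they were -0.33 to 1.43 for miR-146a-5p and -1.29 to 1.45 for miR-142a-3p. With protein they were -0.42 to 0.13 for miR-146a-5p, -1.57 to 0.87 for miR-155-5p and -0.030 to 0.99 for miR-21a-5p. Over both sexes they were -0.32 to 0.14 for miR-21a-5p, -0.43 to 0.23 for miR-223-3p and -0.76 to 0.13 for miR-451a. Over both treatments they were -0.23 to 0.58 for miR-146a-5p, -0.14 to 0.33 for miR-21a-5p and -0.52 to 0.36 for miR-451a. The interaction of miR-223-3p ran from -1.07 to 0.36.

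Replicate numbers gave no clear pairing of the libraries, and a weak one stays open for the protein in females. After group means were removed, same-numbered libraries correlated over 0.1 in 1, 1, 0 and 0 of 4 pairs in the 4 comparisons, with a range of -0.116 to 0.149. The own number was the best match in 3, 1, 0 and 0 of 4, and the 3 in females had 0.0988, 0.0991 and 0.103.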

Other observations

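Of the 11 other abundant entries with a miRBase number of 2000 or more, the log2 folds with protein in females were -0.19 (SE 0.21) for miR-6236, -0.09 (SE 0.29) for miR-5126, -0.11 (SE 0.38) for miR-3963, -0.37 (SE 0.36) for miR-2137, -0.49 (SE 0.44) for miR-6538, -0.0077 (SE 0.51) for miR-3060-5p, -0.046 (SE 0.51) for miR-3535, -0.42 (SE 0.54) for miR-6238, -2.04 (SE 1.00) for miR-5100, -1.03 (SE 0.59) for miR-3470b and -1.65 (SE 0.78) for miR-5098. None of the 11 passed. That of miR-5100 was 0.40 by edgeR and 0.46 by DESeq2, and without protein-treated female 2 it was -3.27 and passed.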
